A study of Mus musculus with 5 samples.

How the data were processed

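Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of RORγt was run on mouse thymocytes, per the labels' protocols with anti-RORγ antibodies, on total thymocytes of C57BL/6 mice and on CD4 CD8 double-positive (DP) thymocytes of Rorc-/- mice. RORγt is the thymic isoform of the nuclear receptor encoded by Rorc. The 5 samples were untreated wild-type (WT), MRL-871 treated, MRL-248 treated and untreated Rorc-/- thymocytes, and whole chromatin of WT thymocytes. The first 4 each had 1 peak list; the whole chromatin sample was not analysed here. The WT and Rorc-/- samples thus differed in the cells used as well as in genotype.

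Reads were aligned with BWA to mm10 and peaks were called with MACS2, per the submitters' processing notes. Per the file headers the version was MACS 2.1.0.20140616, with a q cutoff of 0.05, reads of 75 bp, 1 read kept per position, and the larger library scaled to the smaller. Per the file headers, the WT, MRL-871 and MRL-248 peaks were each called with the Rorc-/- ChIP library as control, and the Rorc-/- peaks with a pooled input as control. What was pooled there, and whether it was the whole chromatin sample, is not stated. Each call used 1 ChIP library, so no ChIP replicates were pooled. The pileup column is a signal, the number of fragments over the summit, which the authors' caller did not divide by depth. The fold enrichment is a ratio that the authors' caller formed from that pileup and the local control level. The −log10 p and −log10 q values are likewise the authors' deposited values, from a Poisson model of pileup against control. Fold enrichment, pileup and q were used to rank, filter or describe peaks within a list. Where values of 1 site are printed from several lists, each describes its own list and they were not compared. Numbers of peaks past a fixed fold or q are given per list, and these depend on depth. For the depth tests of the closing section, the fragments at each MRL-248 summit were drawn at random down to the depth and fragment length of the other library. A peak was kept if its Poisson p, computed as the caller did, passed the weakest p listed for that library. On simulated sites, lists thinned this way had 0.988 (WT depth) and 0.975 (MRL-871 depth) times the peaks of a new list. Because WT and both compound lists share 1 control library, a chance low in that control can raise all 3 at the same place. A region with a peak in the Rorc-/- library was also less able to enter those 3 lists.

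Depth was taken from the file headers. Reads before and after removal of duplicates were 26396663 and 13510713 for WT, 33419277 and 11531734 for MRL-871, 29080408 and 16489022 for MRL-248, and 24544391 and 17662192 for Rorc-/-. The redundant share was 49%, 65%, 43% and 28% in the same order. The pooled input of the Rorc-/- call had 25699252 reads after duplicates were removed.

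Positions are 1-based and on mm10. Genes came from a RefSeq table of the GRCm38.p6 assembly, whose chromosome coordinates are those of mm10. All 272 names written out in the fixed lists matched it, of which 3 were receptor constant segments and 269 stood for 268 protein-coding genes, since Myb was in 2 lists. The table gives gene boundaries without strand, exons or transcription starts, and no genome sequence was used here. The planned shares of peaks with a ROR response element, at a promoter, in an exon or in an intron were therefore not run. In their place, chosen after the files had been seen, the share of summits within 1 kb of either boundary of a protein-coding gene was computed.

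Peak lists were compared by overlap of at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals, which cover sampling of peaks in 1 library only. A baseline for overlap came from 1000 random placements of the second list within the annotated span of each peak's chromosome. The placements were uniform and were not matched on nearness to genes, open chromatin or multi-copy sequence. Lists that share such a bias can exceed this baseline without shared binding. A simulation of 20 draws with no binding, on a genome of even coverage with the shared control, gave the overlap that the control adds among calls made by chance. The local control level of each peak was worked back from pileup and fold enrichment and divided by the genome background. A level above 2 was called multi-copy, as a label only, since copy number was not measured. For WT and both compound lists that control was the Rorc-/- ChIP library. For each of 14 of the 16 gene lists fixed before the data were examined, genes with a peak over them or within 10 kb were counted and set against 10000 random lists of protein-coding genes of the same size matched on gene length in 20 bins. The other 2 lists were the segments of the T cell receptor alpha and delta locus and of the other antigen receptor loci, which have no such matched background. The random lists were not matched on expression or open chromatin.

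Peaks and genes were named by rules fixed before the data were examined. These were the 10 WT peaks of highest fold enrichment with no Rorc-/- overlap, the top 5 of each other list, the top 5 WT peaks absent from each compound list, the top 5 peaks of each compound list absent from WT, and up to 4 genes per fixed list and library plus those with a peak in some lists only. A peak was described by the protein-coding gene it lay in or else by the nearest gene boundary, since transcription starts were not used. With 1 library per group, no test between conditions was made and no p-value is given. The results were also computed, by choices fixed beforehand, with a 50% reciprocal overlap, summits within 100 bp, the upper 50% of each list by fold enrichment, the same number of top peaks in each list, stricter thresholds, wider gene windows, chromosomes 1 to 19 and X only, and removal of peaks in the Rorc-/- list. Overlap counting was tested on simulated lists of the real sizes, where 100% of 670 planted overlaps were found for WT against MRL-871 and 100% of 670 for WT against MRL-248. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.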

Results

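RORγt binding was mapped by ChIP-seq in mouse thymocytes, in 1 library each of untreated WT, MRL-871 treated, MRL-248 treated and Rorc-/- cells. The compounds are known here by code name, and the labels give no dose or time. The lists held 1340 peaks for WT, 1736 for MRL-871, 4979 for MRL-248 and 118 for Rorc-/-. They covered 449, 525, 2040 and 43.2 kb, from libraries of 13510713, 11531734, 16489022 and 17662192 reads after removal of duplicates. With no replicates, no difference between lists could be set against replicate error, and every interval below is a 95% exact interval over peaks of 1 library. Fold enrichment is the authors' value for each peak and ranks peaks within its own list only.

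The first comparison, WT with Rorc-/- cells, which lack the antibody's target, asked which sites were listed apart from the background of the antibody. In WT, the peaks of highest fold enrichment lay 28.2 kb from Pdcl3 (chromosome 1, 39025093 to 39026044, fold 35.9) and 24.0 kb from Zfp236 (chromosome 18, 82716708 to 82717593, fold 34.0). Next came peaks inside Agfg2 (chromosome 5, 137652284 to 137653557, fold 26.1) and P3h4 (chromosome 11, 100408370 to 100409173, fold 25.3), 0.365 kb from Lrrc58 (fold 24.9), 90.2 kb from Frmd4a (fold 24.1) and inside Colq (fold 23.3). Cry1, which encodes a repressor of the circadian clock, held a peak inside the gene (chromosome 10, 85161705 to 85162252, fold 19.7), followed by peaks 23.7 kb from Iyd (fold 19.4) and 107 kb from Nabp1 (fold 17.2). Rorc itself held a WT peak inside the gene (chromosome 3, 94388117 to 94388665, fold 15.3) and none in the Rorc-/- list. A peak there does not measure the deletion, so it does not check the genotype label.

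In the Rorc-/- list, 37 of the 118 peaks fell between 3000073 and 3038301 on chromosome 9, where the gene table holds no gene, and 15 and 35 fell in the 1 Mb windows that start at 14 and 15 Mb of chromosome 5, which hold Speer4d and Speer4e; these places were named after their values were seen. Its peaks of highest fold enrichment were 28.5 kb from 4933428M09Rik on chromosome X (fold 10.3), 122 kb from Tmx3 (fold 8.66), 257 kb from Cntn6 (fold 7.99), 55.1 kb from Prlhr and 190 kb from Tmem64 (both fold 7.66). Of the WT peaks, 1 of 1340 overlapped a Rorc-/- peak (0.0746%, 0.00189 to 0.415%), against a mean of 0.03 in random placements. The Rorc-/- library was also the control of the WT call, which works against such overlaps. Even so, 12 of the 118 Rorc-/- peaks overlapped an MRL-871 peak (10.2%, 5.37 to 17.1%), against 0.034 in random placements, and 0 an MRL-248 peak. They lay on chromosomes 2 and 9, all 12 at a multi-copy control level, and the MRL-871 peaks there, 0.691% of its list, had folds of 1.27 to 1.59. In all, 85.6% of the Rorc-/- peaks sat at a multi-copy control level.

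Genes of the circadian clock and of the ROR and REV-ERB receptors held WT peaks at 7 of 20 genes. These were Arntl, which encodes the clock activator BMAL1 (chromosome 7, 113207348 to 113208027, fold 16.2), Cry1, Rorc, Nr1d2 (REV-ERBβ, fold 10.7), Clock (fold 9.87), Dbp (fold 7.77) and Npas2 (fold 4.68). As many or more genes were hit in 0.01% of random lists. T cell transcription factors held WT peaks at 9 of 33 genes (0.04% of random lists), led by Bcl6 (fold 9.87), Tcf7, which encodes TCF-1 (fold 7.68), Satb1 (fold 6.32) and Foxo1 (fold 5.58). DP thymocyte identity and recombination genes held them at 7 of 24 genes (0.14% of random lists), namely Cd4 (fold 7.50), Cd8a (fold 7.18), Arpp21 (fold 6.32), Aqp11, Cd24a, Lat and Cd8b1. Coregulators held them at 5 of 22 genes (3.19%), with Ncoa1 (fold 8.29) and Ncoa2 (fold 7.25) first, and survival and cell cycle genes at 4 of 22 (7.56%), namely Pim1 (fold 8.01), Ccnd3 (fold 7.90), Cdk6 (fold 7.54) and Bcl2l1, which encodes the survival factor Bcl-xL (fold 7.39). Counted within 5 kb of a gene boundary, transcription factor genes with a WT peak were 4 and survival genes 2, and within 50 kb of the gene they were 14 and 9, with 11 clock genes; the 5 kb count was chosen after the data were seen, and random lists were drawn at neither distance.

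Other fixed lists held WT peaks about as often as random lists did. No allowance was made for the number of lists, which bears most on the coregulators (3.19%) and survival genes (7.56%) above. The random lists were not matched on expression or open chromatin. The Th17 programme, the helper cell fate that RORγt also directs, held WT peaks at 3 of 33 genes (Furin, Ramp1 and Hif1a; 44.96% of random lists), and cholesterol and lipid metabolism at 3 of 30 (Fdps, Abcg1 and Srebf1; 37.78%). Cd27 was the 1 gene of 18 in the mature T cell and egress list (74.54%). Among markers of other cells, WT peaks lay at Cd79b of 10 B cell genes (51.11%), Cd68 of 12 myeloid genes (54.8%), Klrb1c of 10 NK and innate lymphoid genes (53.56%), and at 0 of 10 thymic epithelial and 0 of 10 erythroid genes. Syp was the 1 gene of 15 in the neuron and liver list kept as a negative comparison (66.29%). Random lists matched to these marker and negative lists had means of 0.629 to 1.04 genes with a peak, so counts of 0 or 1 say little. In the Rorc-/- list, Itgam of the myeloid list was the 1 gene with a peak among all 268 genes of these 14 lists (0.373%), where WT had 43 (16.0%). The Rorc-/- list was also the shorter, at 118 peaks to 1340. Of all 21896 protein-coding genes, 12 had a Rorc-/- peak (0.0548%) and 1562 a WT peak (7.13%).

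**Figure D1:**
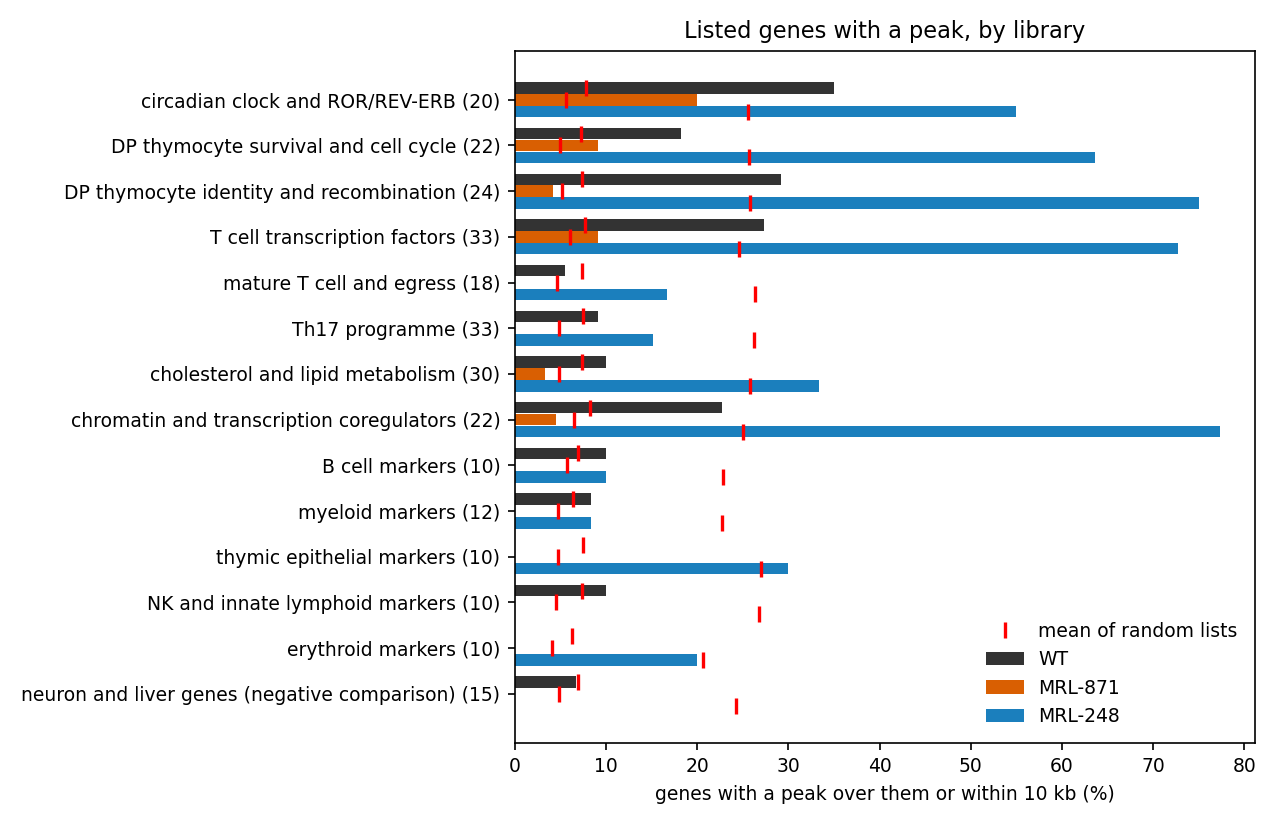
Share of the genes of each fixed list (number of genes in brackets) with a peak over the gene or within 10 kb, for the WT, MRL-871 and MRL-248 libraries, with red ticks at the mean of 10000 length-matched random lists. Circadian genes stood at 7, 4 and 11 of 20 in the WT, MRL-871 and MRL-248 lists, and DP identity genes at 7, 1 and 18 of 24; each bar is 1 library, so there are no error bars.

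In WT, 52.8% of summits (50.1 to 55.5%) lay within 1 kb of a boundary of a protein-coding gene, against 3.67% of random positions. The share was 19.4% (17.5 to 21.3%) with MRL-871, 56.5% (55.1 to 57.9%) with MRL-248 and 5.93% (2.42 to 11.8%) in Rorc-/-. Summits inside a protein-coding gene made up 71.1%, 41.0%, 75.3% and 7.63% in the same order, against 39.2 to 41.1% of random positions.

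**Figure D2:**
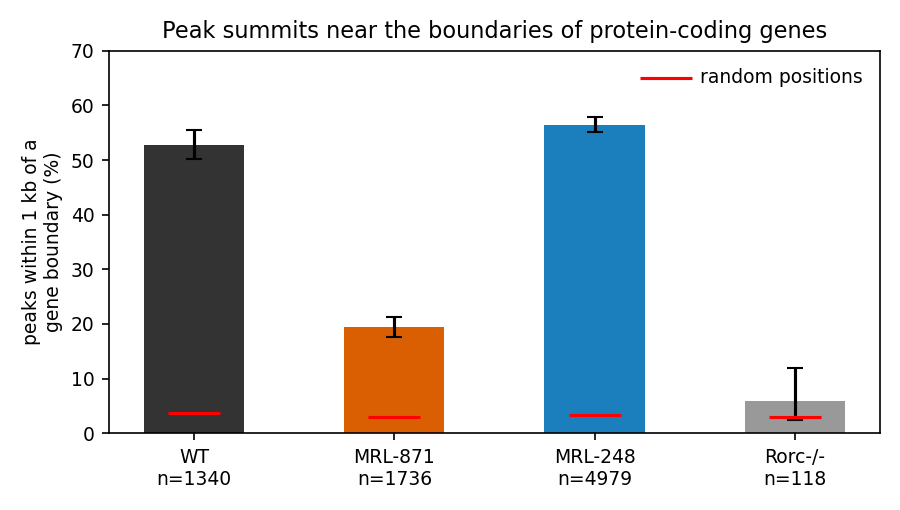
Share of peak summits within 1 kb of either boundary of a protein-coding gene in each library, with exact 95% intervals over peaks (n, peaks), and red lines at the share of random positions. WT and MRL-248 stood at 52.8% and 56.5%, MRL-871 at 19.4% and Rorc-/- at 5.93%.

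The second comparison asked which WT sites were also listed after MRL-871. The peaks at Agfg2 (fold 28.4 in the MRL-871 list), near Zfp236 (fold 19.1) and in Colq (fold 13.4) were among the top 5 of the MRL-871 list, with those 15.5 kb from Adgre5 (fold 23.5) and 3.09 kb from Tmem125 (fold 15.3); all 5 overlapped a WT peak. Of the 10 leading WT peaks, those near Frmd4a, in Cry1 and near Iyd overlapped no MRL-871 peak. Neither did a WT peak between Trbc2 and Trbv31 of the T cell receptor beta locus, whose nearest protein-coding gene is Prss2 (fold 15.0), nor one 125 kb from Supt20 (fold 13.4). In all, 234 of 1340 WT peaks overlapped an MRL-871 peak (17.5%, 15.5 to 19.6%), against 0.592 in random placements. Conversely, 234 of 1736 MRL-871 peaks overlapped a WT peak (13.5%, 11.9 to 15.2%). With summits required to lie within 100 bp the shares were 10.9% and 8.41%, and without multi-copy peaks the first was 11.2%. The random placements, here and below, were uniform, so they are a low baseline for lists that favour gene boundaries or multi-copy sequence.

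Clock genes with a peak in both lists were Arntl, Dbp and Rorc, while Cry1, Clock, Nr1d2 and Npas2 had one in WT and not with MRL-871, and Per2 the reverse. The MRL-871 count was 4 of 20 (2.03% of random lists). Of DP identity genes, the 7 with a WT peak had none with MRL-871, whose 1 gene of 24 was Dntt (71.99%), which encodes terminal deoxynucleotidyl transferase. Such absence was not particular to these genes, since 1106 of all 1340 WT peaks overlapped no MRL-871 peak. MRL-871 peaks lay at 12 of the 268 listed genes (4.48%) and at 5.06% of all protein-coding genes. Bcl6, Ets1 and Runx1 were the 3 transcription factor genes of 33 (32.35%), and Cdk6 and Bcl2l11 the 2 of 22 survival and cell cycle genes (29.69%). Ncor2 was the 1 of 22 coregulators (76.8%) and Ppard the 1 of 30 in cholesterol and lipid metabolism (77.71%). MRL-871 peaks lay at 0 genes of the Th17, mature T cell, B cell, myeloid, thymic epithelial, NK, erythroid and neuron and liver lists. Within 5 kb of a gene boundary, MRL-871 peaks lay at 1 clock gene and at 0 DP identity, 0 transcription factor and 0 coregulator genes, and within 50 kb of the gene at 8 clock, 2 DP identity, 6 transcription factor, 4 coregulator, 4 survival and 4 Th17 genes.

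MRL-871 peaks of highest fold enrichment with no WT overlap lay outside protein-coding genes, 124 kb from Fgf14 (fold 13.3), 682 kb from Gm40892 (fold 12.8), 17.3 kb from Mrgprd (fold 12.8), 195 kb from H2ab1 on chromosome X (fold 11.5) and 15.9 kb from Dnmt3a (fold 10.2); none of these 5 overlapped an MRL-248 peak. Of the MRL-871 list, 268 peaks (15.4%) fell in the 5 windows of 1 Mb with at least 20 MRL-871 peaks each, which held 59 WT and 119 MRL-248 peaks, and 23.6% sat at a multi-copy control level against 9.93% in WT. The window with the most held 81 MRL-871 peaks, between 114492318 and 114635926 of chromosome 6, where the gene table holds no gene, with 0 in WT and 9 with MRL-248.

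The third comparison asked the same of MRL-248. Its leading peaks, at Agfg2 (fold 36.7 in the MRL-248 list), near Zfp236 (fold 24.9), near Lrrc58 (fold 18.4), 4.27 kb from Gm8439 (fold 15.6) and in Colq (fold 15.2), all overlapped WT and MRL-871 peaks. Of the 10 leading WT peaks, the one near Frmd4a overlapped no MRL-248 peak; the next WT peaks absent from that list lay near Supt20, inside Gm525 (fold 12.6) and Phactr2 (fold 11.5), and 126 kb from Xxylt1 (fold 11.1). MRL-248 peaks of highest fold enrichment with no WT overlap lay inside Sfpq (fold 10.6), Klf3 and the overlapping Gm38457 (fold 10.3), Med7 (fold 9.85), Wasf2 (fold 9.73) and Atl2 (fold 9.34). In all, 747 of 1340 WT peaks overlapped an MRL-248 peak (55.7%, 53.0 to 58.4%), against 2.62 in random placements, and 743 of 4979 MRL-248 peaks overlapped a WT peak (14.9%, 13.9 to 15.9%). At 1340 top peaks in each list these shares were 28.7% and 28.0%, and with summits within 100 bp 28.2% and 7.59%.

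All 7 clock genes with a WT peak had one with MRL-248, which added Per1, Per2, Rora and Tef (11 of 20, 0.44% of random lists). DP identity genes had MRL-248 peaks at 18 of 24, but not at Cd4. By fold in the MRL-248 list, Lat (7.98), Cd24a (6.60), Cd8a (6.05) and Slamf6 (5.60) came first. Rag1 and Rag2, whose recombinase assembles receptor genes, shared 1 peak (fold 4.98). Lower still were Zap70 (fold 4.44), Cd3d (fold 4.28), Lck (fold 3.92) and Ptcra (fold 3.89). The Lck and Ptcra peaks had pileups of 12, where 10 was the lowest of that list. T cell transcription factors had MRL-248 peaks at 24 of 33. These were led by Bcl6 (fold 7.89), Tcf7 (fold 7.80), Zbtb7b (fold 7.16) and Satb1 (fold 7.10). Coregulators had MRL-248 peaks at 17 of 22, led by Hdac3 (fold 8.09), Smarca4 and Tet3. For each of these 3 lists, 0 of the 10000 random lists had as many genes with a peak. Of all 21896 protein-coding genes, 23.7% had an MRL-248 peak. The random lists were not matched on expression or open chromatin, so an excess over them need not be particular to T cell genes. Survival and cell cycle genes followed at 14 of 22 (0.03% of random lists). They were led by Pim1 (fold 7.78), Ccne2 (fold 6.85), Cdk6 (fold 6.30) and Bax (fold 6.22). The others included Bcl2l1, Myc, Bak1, Bbc3, Bcl2l11, Cdkn1b and Cdkn2d.

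MRL-248 peaks also lay at 10 of 30 cholesterol and lipid genes (22.35%), with Insig1 first (fold 9.03), and at 5 of 33 Th17 genes (95.64%), namely Hif1a (fold 8.97), Rbpj, Ramp1, Furin and Batf. Cd27, Cd69 and Ccr7 were the 3 of 18 mature T cell genes (89.06%). Markers of other cells gave Cd79a of 10 B cell genes (92.94%), Cd68 of 12 myeloid genes (95.34%), Ccl25, Dll4 and Epcam of 10 thymic epithelial genes (53.33%), Tfrc and Epor of 10 erythroid genes (64.37%), and 0 of the NK and the neuron and liver genes. At 1340 top peaks the MRL-248 counts were 8 clock, 5 DP identity, 15 transcription factor, 8 coregulator and 6 survival genes, against 7, 7, 9, 5 and 4 in the WT list of that length. There they also fell to 3 cholesterol and lipid and 2 Th17 genes, and to 0 mature T cell, B cell, thymic epithelial and erythroid genes. Within 5 kb of a gene boundary the whole MRL-248 list had 7 clock and 3 Th17 genes. Within 50 kb of the gene it had 9 Th17, 7 mature T cell, 4 B cell and 3 myeloid genes. At that distance it also had 5 thymic epithelial, 1 NK, 4 erythroid and 3 neuron and liver genes.

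The fourth comparison set the compounds side by side, with doses and times not given. Of MRL-871 peaks, 380 of 1736 overlapped an MRL-248 peak (21.9%, 19.96 to 23.9%), against 2.39 in random placements; this was 12.2% at 1340 top peaks each. Of WT peaks, 178 (13.3%) overlapped a peak of both compound lists, 56 (4.18%) of MRL-871 alone, 569 (42.5%) of MRL-248 alone and 537 (40.1%) of neither. In the top 10% of WT peaks by fold enrichment, 35.1% (27.0 to 43.8%) overlapped an MRL-871 peak and 76.1% (68.0 to 83.1%) an MRL-248 peak. Between the 25th and 50th percentile these shares were 7.76% (5.13 to 11.2%) and 49.0% (43.5 to 54.4%). In the lowest 10% they were 44.0% and 50.7%, with 65.7% of the peaks at a multi-copy control level, and without those 10.9% (3.62 to 23.6%) and 50% (34.9 to 65.1%). In the simulation with the shared control and even coverage, each pair of the 3 lists shared 0 peaks in 20 draws. The simulated lists had means of 233 to 237 WT, 371 to 376 MRL-871 and 684 to 688 MRL-248 peaks. These are fewer than in the real lists, which leaves less room to overlap. All were called with no binding, so part of each real list may be such calls. The control is 1 library and could not be split, so part of the excess overlap may come from it.

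**Figure D3:**
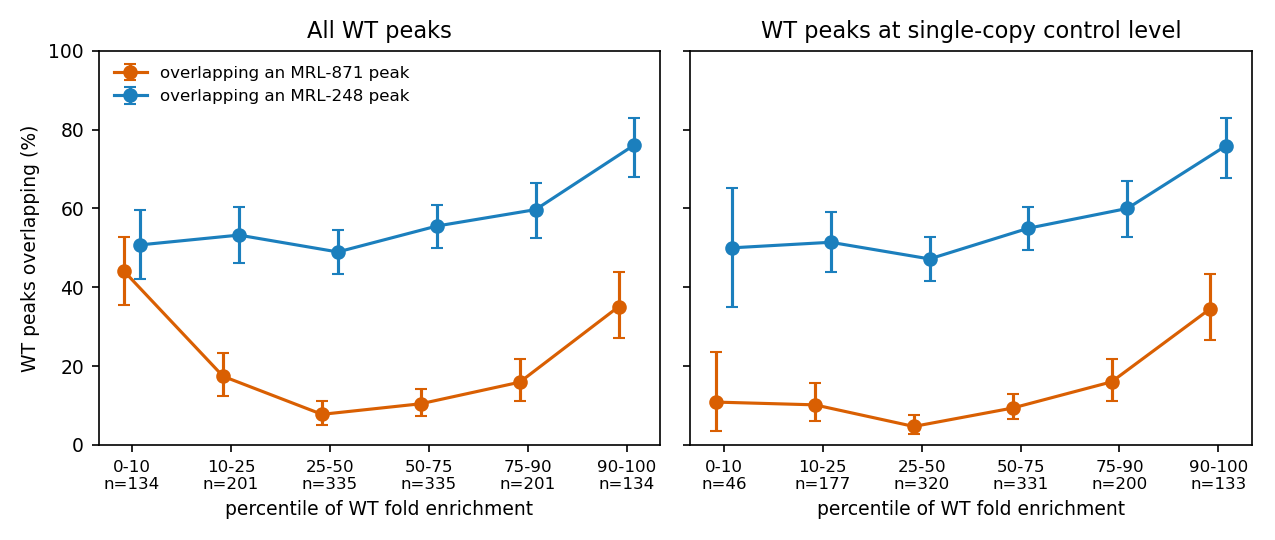
Share of WT peaks overlapping an MRL-871 or an MRL-248 peak, by percentile of WT fold enrichment, for all WT peaks (left) and for those at a single-copy control level (right); bars are exact 95% intervals over n peaks. In the top 10% of WT peaks the shares were 35.1% and 76.1% in the left panel.

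At the 3' end of the T cell receptor alpha locus, 1 peak was in all 3 lists. It lay between Trac, the constant segment, and Dad1, in the stretch where the Tcra enhancer is known to lie, at 54227375 to 54228038 of chromosome 14 in WT (fold 7.14), 54227480 to 54227754 with MRL-871 (fold 8.45) and 54227369 to 54227809 with MRL-248 (fold 8.95). Folds in this paragraph are each list's own and were not compared between lists. In the beta locus, the stretch between Trbc2 and Trbv31, where the Tcrb enhancer is known to lie, held 2 WT peaks. The one from 41553055 to 41553628 of chromosome 6 (fold 15.0) overlapped MRL-248 peaks only, and the one from 41554336 to 41555092 (fold 10.3) overlapped an MRL-871 peak (41554355 to 41554628, fold 9.11) and MRL-248 peaks. Over the whole alpha and delta locus of 202 segments there were 2 WT, 3 MRL-871, 5 MRL-248 and 0 Rorc-/- peaks, and in the beta locus 3, 1, 7 and 0. The gamma, heavy chain and lambda loci had 0 in each list, and the kappa locus 1, with MRL-871.

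**Figure D4:**
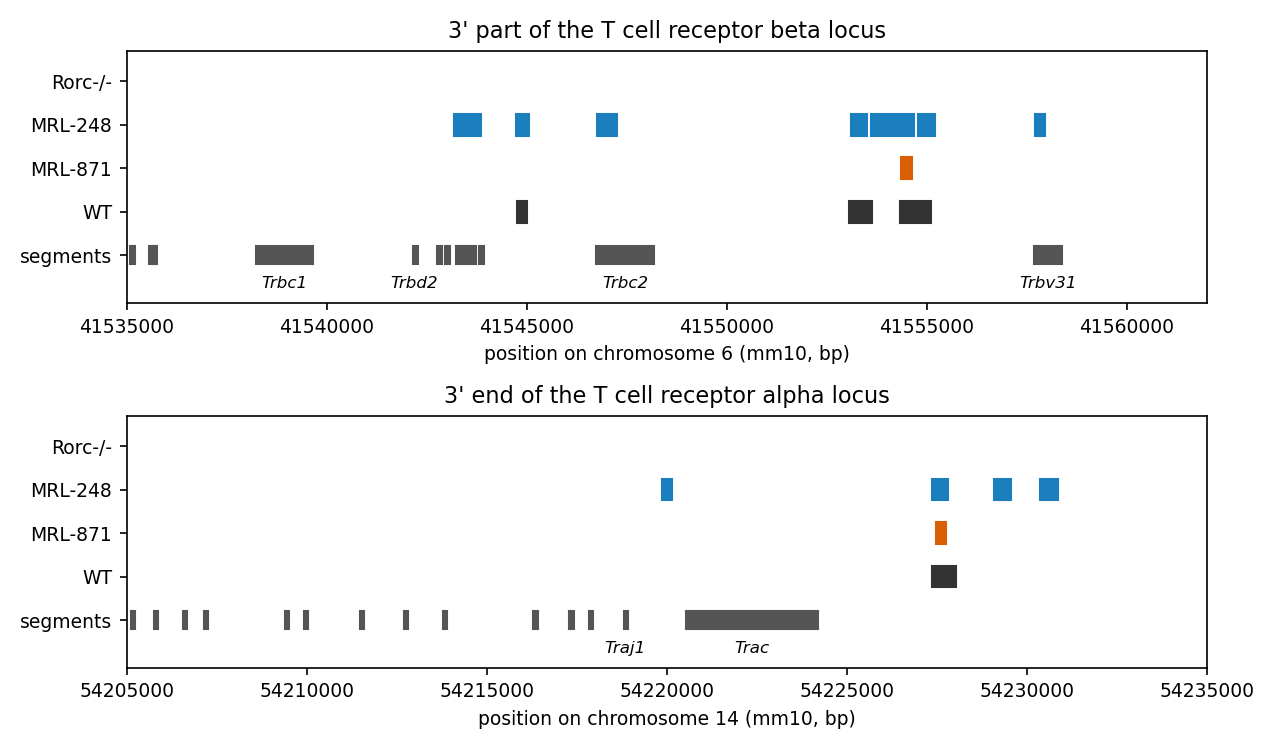
Peaks of the 4 libraries (boxes) over the 3' part of the T cell receptor beta locus (top) and the 3' end of the alpha locus (bottom), with annotated segments in grey; positions in bp on mm10. WT, MRL-871 and MRL-248 each have a box between Trbc2 and Trbv31 and another beyond Trac, and Rorc-/- has none.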

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

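Alternatives were planned before the data were examined, except those on multi-copy peaks, dense windows and gene boundaries, which were chosen after seeing the data. Planned shares of peaks with a ROR response element (with their windows, core motif and filters), shares at a promoter (within 1 or 5 kb of a transcription start) and listed genes by distance to a transcription start were not run. No paired analysis was possible because each group had 1 sample. More WT peaks overlapped an MRL-248 than an MRL-871 peak in every alternative run, but the order among the other shares did not always hold. MRL-871 in MRL-248 lay above WT in MRL-871 in the main run and below it at equal list length, at 12.2% against 13.4%. The shares moved, and the cause was not tested beyond what each alternative leaves out. Pileups of 8 to 10 were the lowest listed for the 3 lists called against Rorc-/-, so a site missing from a list may lie just under that limit; at 1340 top peaks each, 13.4% and 28.7% of WT peaks overlapped MRL-871 and MRL-248 peaks.

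The share of WT peaks overlapping an MRL-871 peak was 11.8% under 50% reciprocal overlap, 10.9% for summits within 100 bp, 13.0% for the upper 50% of both lists by fold enrichment, 13.4% for equal list length, 11.2% without multi-copy peaks and 14.1% without the dense windows. For WT in MRL-248 it was 31.8% (reciprocal), 28.2% (summits), 60.2% (upper 50% of WT), 47.4% (upper 50% of both), 28.7% (equal length) and 51.6% (without multi-copy). MRL-871 in MRL-248 gave 12.1% (reciprocal), 12.2% (summits), 25.2% (upper 50% of MRL-871), 18.7% (upper 50% of both), 12.2% (equal length), 18.5% (without multi-copy) and 19.1% (without dense windows). MRL-871 in WT gave 9.10% (reciprocal), 8.41% (summits), 16.0% (upper 50% of MRL-871), 10.2% (upper 50% of both) and 10.2% (without multi-copy). MRL-248 in WT gave 8.56% (reciprocal), 7.59% (summits), 20.5% (upper 50% of MRL-248), 12.9% (upper 50% of both), 28.0% (equal length) and 13.8% (without multi-copy). The single overlap of WT with Rorc-/- was lost, at 0, in the upper 50% of WT peaks, the upper 50% of both lists and without multi-copy peaks.

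At a −log10 q of at least 5, 687 WT, 548 MRL-871, 2340 MRL-248 and 71 Rorc-/- peaks were left, and at a fold enrichment of at least 5, 897, 894, 1832 and 25. Within 5 kb of a gene boundary lay 68.6% of WT, 32.6% of MRL-871 and 74.2% of MRL-248 summits. The 1 kb share was 22.3% for the upper 50% of MRL-871 and 61.9% for that of MRL-248, and 21.6% for MRL-871 without multi-copy peaks. Genes of the 14 lists with a peak within 50 kb numbered 69 for WT and 37 for MRL-871, 4 for MRL-871 within 5 kb of a gene boundary, and 48 for MRL-248 at equal list length. The other 35 alternatives of these results stayed within their interval or within 1.5 times the count. Among counts for single gene lists, 121 alternatives stayed within 1.5 times the main count, 28 gave a higher and 19 a lower one.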

Other observations

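All tests and places in this part were chosen after the results they bear on had been seen. Genes for small RNAs also carried peaks. No random baseline was drawn for these counts, and the lists differ in length. The span of the 5S rRNA array of chromosome 8, where 48 annotated rRNA genes lie between 123538784 and 123622046, held 10 WT, 48 MRL-871, 31 MRL-248 and 0 Rorc-/- peaks in all. Counted within 500 bp of the gene, 10 of 65 rRNA genes had a WT, 41 an MRL-871 and 31 an MRL-248 peak. Of 430 tRNA genes, 17 had a WT, 11 an MRL-871 and 69 an MRL-248 peak, from 10, 5 and 52 peaks in that order. Of 1228 miRNA genes, 7, 6 and 54 did, and of 1004 snRNA genes 6, 0 and 19; of 1340 snoRNA genes, 8 had a WT, 8 an MRL-871 and 21 an MRL-248 peak.

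Chromosome X held 23 WT peaks (1.72%, 1.09 to 2.56%), 131 MRL-871 peaks (7.55%, 6.35 to 8.89%) and 47 MRL-248 peaks (0.944%, 0.694 to 1.25%), while it makes up 6.31% of the annotated span of the chromosomes. The 1301 of 1736 MRL-871 peaks that overlapped neither a WT nor an MRL-248 peak lay within 1 kb of a gene boundary in 10.5% of cases (8.84 to 12.2%), and the 201 shared with MRL-248 but not WT in 56.2% (49.1 to 63.2%).

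Fewer WT peaks overlapped an MRL-871 peak (17.5%) than an MRL-248 peak (55.7%). Lower depth of the MRL-871 library as the whole cause is argued against, since the MRL-248 list thinned to the depth and fragment length of MRL-871 still overlapped a mean of 46.3% of WT peaks (44.7 to 48.6% in 100 draws), against 17.5% (15.5 to 19.6%) for MRL-871. With summits within 100 bp these were 24.1% and 10.9% (9.28 to 12.7%). The thinned MRL-248 list still held a mean of 3467 peaks against 1736 for MRL-871, and a longer list can overlap more WT peaks. At 1340 top peaks in each list, unthinned, the shares were 28.7% for MRL-248 and 13.4% for MRL-871. A weaker pull-down in the MRL-871 library remains open, since its single-copy peaks found in no other list lay near gene boundaries in 11.6% of cases (9.72 to 13.7%), against 45.5% (41.1 to 49.9%) for such WT peaks and 3.03% for random positions. The compound remains open too, as a hypothesis, and with 1 library per condition it and the pull-down cannot be told apart. The redundant share was also higher in the MRL-871 library, at 65% against 49% in WT and 43% with MRL-248. Whether that difference played a part was not tested.

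The MRL-248 list was longer than the WT list, by 4979 peaks to 1340. Higher depth of the MRL-248 library as the whole cause is argued against, since that list thinned to the depth and fragment length of WT kept a mean of 3993 peaks (3918 to 4078 in 100 draws). Background calls at random positions as the whole cause are argued against by the 55.3% (53.6 to 56.9%) of its unshared single-copy peaks near a gene boundary, where random positions gave 3.30%. Background calls that themselves favour gene boundaries would pass that test, so it does not bear on them. Such calls, a stronger pull-down and the compound all remain open and were not tested. A part played by calls at random positions stays open too, since the simulation with no binding called means of 684 to 688 MRL-248 peaks.

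MRL-871 peaks crowded into 5 windows of 1 Mb, with 81, 67, 53, 43 and 24 peaks, where WT had 0, 35, 12, 9 and 3 and MRL-248 had 9, 67, 37, 5 and 1, so the crowding in the windows of 67 and 53 was not particular to MRL-871. Sequence present in more copies than the assembly, or mapped from several copies, is a candidate explanation for where they lie, since the control was more than 2% above the genome background at 97.0% of these peaks (94.2 to 98.7%) against 69.3% (66.9 to 71.7%) elsewhere. At the multi-copy level of above 2 times the background the shares were 67.9% (62.0 to 73.5%) and 15.5% (13.7 to 17.4%), but 43.2% in the window of 81 and 30.2% in that of 53, whose median levels of 1.69 and 1.56 lay below it; since 48 of those 53 lay in the span of the 5S rRNA array, a level below 2 does not rule out repeated sequence. Why MRL-871 had more peaks than WT in these windows was not decided. The control was the Rorc-/- ChIP library and not an input, so a raised level there does not by itself show copy number. A copy number particular to the Rorc-/- control was not tested. That library was the control of both lists, so this alone would not set them apart. The compound at these windows stays open with 1 library per condition.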
